A study of Mus musculus with 17 samples.

How the data were processed

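The series holds 17 sequencing libraries from mouse testis in 10 groups. Wild-type and Mael-/- testes of the 129SvJae strain gave libraries of small RNA of 15 to 50 nt, of ribosome footprints of 26 to 34 nt and of mRNA, each with 2 libraries per genotype. Anti-MAEL immunoprecipitation of RNA gave 2 long-RNA libraries, 1 library of 50 to 150 nt and 1 of 15 to 50 nt, and IgG gave 1 long-RNA library. Groups were taken from the sample labels. Nothing in the labels says that the libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

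The deposited files hold counts of reads per feature, not normalized. The submitters' processing notes name CASAVA 1.8, Bowtie2 2.0.6, TopHat2 2.0.7 and genome build mm9, with no role given for each. Per the labels' protocols, long-RNA libraries came from a kit that does not keep the strand and small RNA libraries from a kit that does. Whether the deposited counts use strand, and how reads that match several features were assigned, is not given in the sources used here, so overlapping, antisense and near-identical features are uncertain. The tables of small RNA and immunoprecipitates list 37991 Ensembl transcripts and 465 entries at 214 piRNA loci, and the immunoprecipitate tables also list 2 entries named by GenBank records. Counts in the mRNA and footprint tables were above 0 only among the 18286 transcripts with a coding size, and the other 19705 transcripts held 0 counts. These tables count the coding part of a transcript, judged from their size columns, while the immunoprecipitate tables count whole transcripts.

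Where a piRNA locus had several entries, the one with the most counts stood for the locus. Library totals on that basis ranged from 4831638 to 44416966 counts for small RNA, from 4130509 to 15372210 for mRNA and from 1668197 to 5009051 for footprints. The long-RNA immunoprecipitates held 5747210 and 10863053 counts with anti-MAEL and 7785650 with IgG. The size-selected immunoprecipitates held 68922710 counts at 50 to 150 nt and 172728187 at 15 to 50 nt. Intervals of single shares are exact binomial intervals at 95% confidence, and the floor for a count of 0 is 3 counts in each library. Both cover counting error only, because reads without molecular identifiers are not independent molecules. Levels are given in CPM, depth-scaled counts relative to library totals, which in the fit of 5 libraries cover coding transcripts alone. Standard deviations (SD) are over the 2 libraries of a group.

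Before averaging, the libraries of each group were compared by a chi-square statistic over features with at least 20 counts. It ranged from 3.30 per degree of freedom in Mael-/- footprints to 51.5 in the anti-MAEL immunoprecipitates, so no pair agreed within sampling noise and none was treated as 1 library.

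Differences were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test, with TMM scaling, the filterByExpr filter and Benjamini-Hochberg adjustment, at an adjusted p of 0.05. Each genotype comparison used the 4 libraries of its assay, with genotype as the only term and no replicate block. Translational efficiency was tested as the interaction of assay and genotype over 8 libraries. Anti-MAEL was set against IgG and against wild-type mRNA in a fit of 5 libraries over coding transcripts. The single IgG library is there assumed to vary like the others. The piRNA loci are missing from the mRNA tables, so for them anti-MAEL was set against IgG in a fit of 3 libraries. The size-selected immunoprecipitates have 1 library each and were not tested. Lists were tested with camera of limma 3.58.1, with a preset correlation of 0.01 and a prior count of 2, then with an estimated correlation and with fry. DESeq2 1.42.0 was an alternative test. Differences between classes of loci were tested with two-sided permutation tests of 100000 resamples. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 did the rest, with a pseudocount of 0.5 CPM for log2 ratios.

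The tests were tried on simulated counts with 200 changed features. Of simulated 4-fold changes, 38% were recovered for small RNA, 63% for mRNA, 83% for footprints, 27% for translational efficiency and 52% for anti-MAEL over IgG with 3 libraries. Of 2-fold changes, 1% were recovered for small RNA, 5% for mRNA, 53% for footprints and 0% for translational efficiency. False calls made up 5 of 44 calls in simulated small RNA and 13 of 81 in mRNA.

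The groups, designs, alternatives and the rule for named features were fixed before the data were examined. The rule took called features with a mean of at least 5 CPM and no overlap between groups, 8 with the largest change in each direction. It was limited to 2 transcript IDs per direction because the files pair no gene symbols with them. Of the transcript IDs, 0 matched the reference tables, so the fixed lists of piRNA pathway proteins, germ cell stages and other cell types could not be tested, and Mael itself was not analysed here by name. The piRNA loci were grouped after the data were examined into 100 named by a chromosome band and 114 named by a gene. A list of small RNA features holds the 50 piRNA loci and transcripts over 300 nt with the most counts in the 15 to 50 nt anti-MAEL immunoprecipitate, a rank by abundance that does not show binding. The alternatives were other scalings, other filters, DESeq2, all entries per locus, other libraries in the fit, left-out replicates, a replicate block and the added settings described with their values. The RefSeq table is of another build, so no coordinates are given.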

Results

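Small RNA, mRNA and ribosome footprints were compared between wild-type and Mael-/- mouse testis, and RNA precipitated with anti-MAEL was compared with IgG background. Mael encodes Maelstrom, a germ cell protein needed for transposon silencing, and piRNAs are the small RNAs that guide PIWI proteins in germ cells. In wild type, band-named piRNA loci took 79.0% ± 0.539 (SD, n = 2) of small RNA counts and gene-named loci 3.82% ± 0.0133. In Mael-/- these shares were 65.8% ± 5.37 and 6.12% ± 0.393. A large part of the gene-named share lay at 1 locus, pi-D10Wsu102e, with 16304 CPM in wild type and 34407 CPM in Mael-/-. With TMM scaling its log2 fold change was -0.12 and did not pass the test (edgeR quasi-likelihood, adjusted p = 0.915). Coding transcripts took 5.39% ± 0.110 of small RNA counts in wild type and 11.5% ± 2.19 in Mael-/-. As background, gene-named loci mostly lie in 3′ untranslated regions of genes and band-named loci are mostly intergenic clusters of meiotic cells. The level of Mael itself, which would check the genotype labels, was not analysed here.

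**Figure D1:**
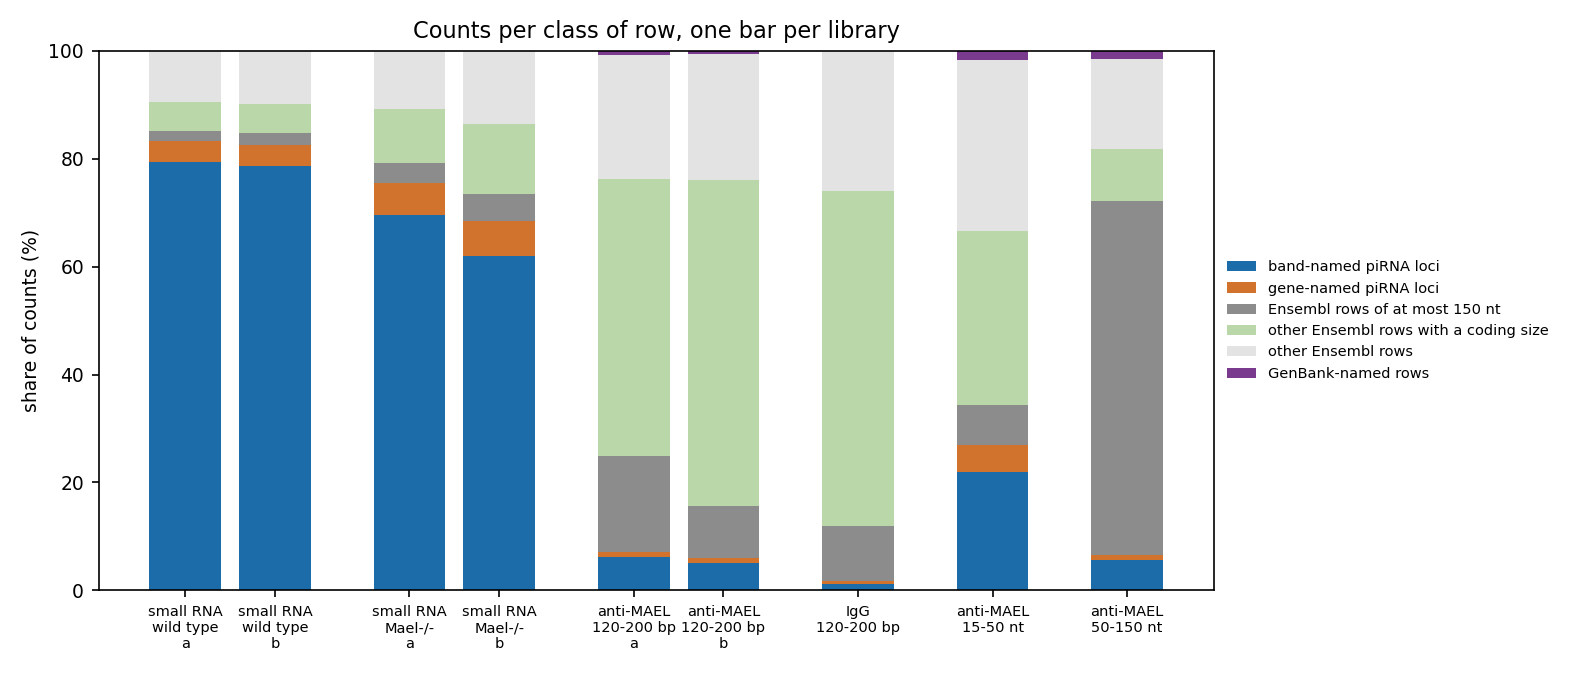
Share of counts (%) in each class of feature for the small RNA and immunoprecipitation libraries. Band-named loci averaged 79.0% of wild-type and 65.8% of Mael-/- small RNA counts.

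The first comparison asked how small RNAs changed without MAEL. Relative to the bulk of measured features, band-named piRNA loci were lower in Mael-/- testis, with 94 of 99 below 0 and a median log2 fold change of -1.72 (interquartile range -1.96 to -1.25). Of these loci, 18 fell and 0 rose (edgeR quasi-likelihood, adjusted p under 0.05; DESeq2 called 76 lower and 2 higher). Gene-named loci went both ways around a median of -0.02, and 15 of 114 rose while 10 fell. Adjusted over the list alone, the counts were 3 higher and 67 lower for band-named loci, and 26 higher and 28 lower for gene-named loci. The lists were formed after the data were examined, so these counts are not independent of that choice. The medians differed by -1.70 (two-sided permutation test over loci, p = 1e-05, the smallest 100000 resamples give; adjusted 1e-05 over 2 comparisons). Loci are not independent replicates.

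Among gene-named loci the largest rises were at pi-Trim71, pi-Igf2bp1, pi-Fbxo41, pi-Tet3, pi-Ankrd11, pi-Uhrf1bp1, pi-Klf13 and pi-Foxo3. All 15 risen loci were scarce in wild type, at 1.55 to 12.7 CPM. They lay outside the 24 gene-named loci with small RNA denser than the 99th percentile of coding transcripts over 300 nt in every library. Fragments of mRNA were therefore not told apart from piRNAs at the risen loci. The pi-Trim71 locus went from 4.02 ± 0.963 to 46.0 ± 12.2 CPM (SD, n = 2), with a scaled log2 fold change of 2.20 ± 0.438 (SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0187). At pi-Tet3, named for a methylcytosine dioxygenase gene, the level went from 6.11 ± 0.462 to 57.8 ± 16.0 CPM. The deepest falls were at pi-Cdc42ep3, from 81.7 ± 9.14 to 4.43 ± 1.35 CPM, and at pi-Wdfy3, from 144.1 ± 9.17 to 13.3 ± 0.652 CPM. Their log2 fold changes were -5.44 ± 0.506 and -4.58 ± 0.537 (SE; edgeR quasi-likelihood, adjusted p = 0.00130 and 0.00176), and pi-Ccdc117 fell by 2.67. Among band-named loci, 7-qF3-246 fell by 3.40 on the log2 scale (edgeR quasi-likelihood, adjusted p = 0.00768), and 10-qC2-545, 11-qE1-3997, 4-qB3-3994 and 10-qA3-2592 also fell. The locus 11-qE1-3997 was the most abundant of these, at 3722 ± 52.6 CPM in wild type and 1231 ± 98.2 CPM in Mael-/-. The locus with the most counts, 17-qA3.3-26735, took 13.6% ± 1.11 of wild-type and 13.7% ± 0.517 of Mael-/- counts, and its log2 fold change of -1.19 did not pass the test (edgeR quasi-likelihood, adjusted p = 0.286). The next, 2-qE1-35981 and 6-qF3-28913, took 6.29% ± 0.189 and 5.15% ± 0.232 in wild type against 4.75% ± 0.410 and 3.35% ± 0.522 in Mael-/-.

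**Figure D2:**
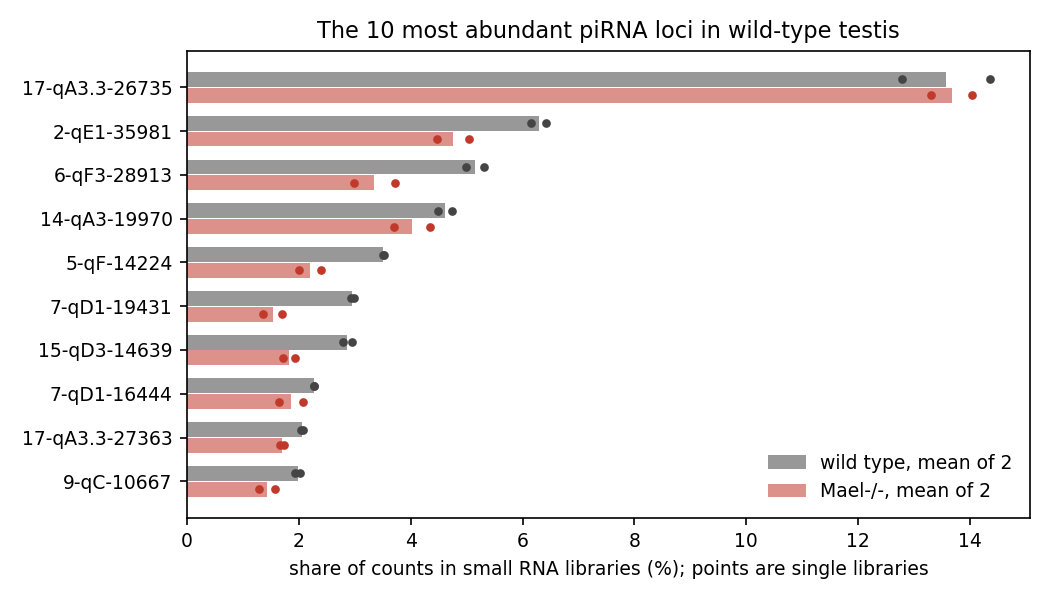
Share of small RNA counts (%) at the 10 most abundant piRNA loci; bars are means of 2 libraries and points single libraries. The locus 17-qA3.3-26735 took 13.6% of wild-type and 13.7% of Mael-/- counts.

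Over all 9906 features tested in small RNA, 378 were higher and 346 lower in Mael-/-. The transcripts ENSMUST00000122512 (184 nt) and ENSMUST00000083808 (133 nt) fell most, by 6.86 and 6.74 on the log2 scale, with near-identical counts, so reads may be shared and each value is uncertain. The transcripts ENSMUST00000075573 and ENSMUST00000099046 rose, with log2 fold changes of 5.78 and 5.61. The list of 50 features with the most counts in the 15 to 50 nt anti-MAEL immunoprecipitate had a median of -0.08 with 0 members called (camera, adjusted p = 0.131; 0.923 with an estimated correlation). Camera placed band-named loci below other features (adjusted p = 1.13e-25), a call lost with an estimated correlation (adjusted p = 0.795), and gene-named loci gave adjusted p = 0.521.

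Scaling set the balance of these calls. With library totals in place of TMM, which differ by -1.22 on the log2 scale, 94.6% of called features were higher (2449 against 139), compared with 52.2% under TMM and 39.4% under size factors. The median of band-named loci was then -0.57, with 11 called higher and 46 lower, and that of gene-named loci 1.23. The counts also rested on single libraries. Without wild-type replicate a, 27 features were higher and 51 lower, with 0 band-named loci lower and 0 gene-named loci higher, and without wild-type replicate b the counts were 128, 204, 4 and 0. Without Mael-/- replicate a they were 396, 1067, 94 and 13, and without Mael-/- replicate b 1218, 672, 80 and 46. The difference between the classes stayed between -2.07 and -1.44 in these 4 fits. It also varied with how loci of like level were chosen: among loci with a mean of 100 to 3000 CPM over the 4 libraries it was -1.56, and among loci at that level in wild type -0.41.

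**Figure D3:**
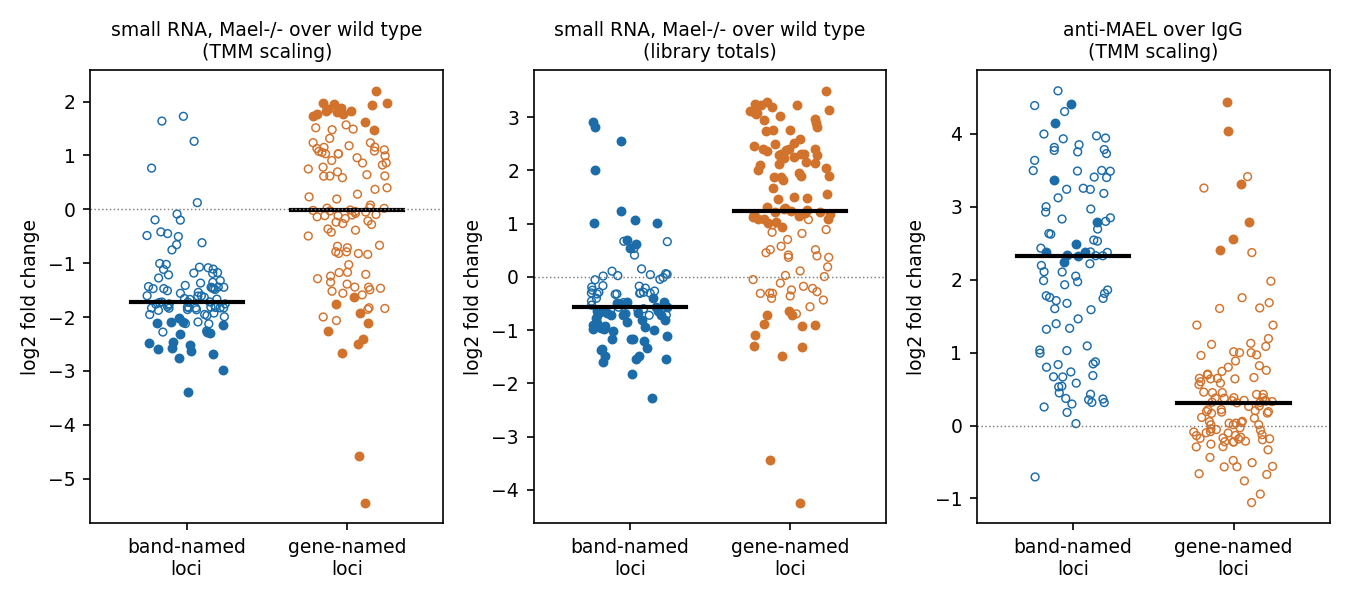
Log2 fold changes of piRNA loci by class, in Mael-/- over wild-type small RNA with TMM scaling and with library totals, and in anti-MAEL over IgG; filled points have an adjusted p under 0.05 and black lines are medians. Band-named loci have medians of -1.72, -0.57 and 2.33.

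The next comparison asked which RNAs anti-MAEL carried beyond IgG. Band-named piRNA loci took 5.65% ± 0.787 (SD, n = 2) of anti-MAEL counts and 1.11% (exact 95% interval 1.10 to 1.12) of IgG counts, and gene-named loci 0.877% ± 0.0313 and 0.540%. Of band-named loci, 98 of 99 were above IgG, with a median log2 fold change of 2.33. The test called 10 of them higher and 0 lower, and 76 and 1 when adjusted over the list alone. Of gene-named loci, 77 of 113 were above IgG, with a median of 0.31, 6 called higher and 18 adjusted over the list alone. The medians differed by 2.02 (two-sided permutation test over loci, p = 1e-05). Here too, loci are not independent replicates, and the classes were formed after the data were examined. Among loci past the test the gene-named pi-Eif2c2 had the largest fold change, at 472.5 ± 21.2 CPM with anti-MAEL and 28.4 CPM with IgG, a log2 fold change of 4.44 ± 0.699 (SE; edgeR quasi-likelihood, adjusted p = 0.0187). The band-named 8-qC5-2209 stood at 767 ± 95.6 against 47.7 CPM and 9-qF4-150 at 507 ± 57.1 against 37.8 CPM. The loci pi-BC026590, 13-qA3.1-213, pi-Ipmk, 4-qD2.2-2182 and pi-Phf20 were also higher. Camera gave adjusted p = 1.62e-49 for band-named loci, 8.69e-05 for gene-named loci and 7.15e-61 for the 50 features most abundant in the 15 to 50 nt anti-MAEL immunoprecipitate, of which 14 were called higher. All 3 calls were lost with an estimated correlation (adjusted p = 0.408, 0.432 and 0.408). The list of 50 was ranked on an anti-MAEL library and holds 22 band-named and 4 gene-named loci, so its result is not independent support. With library totals the calls were 2 band-named and 0 gene-named loci, and with DESeq2 66 and 11. With 1 IgG library, the spread of the background was not measured.

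Among coding transcripts in the fit of 5 libraries, 108 of 12431 were higher with anti-MAEL than with IgG and 0 were lower (edgeR quasi-likelihood; 723 at an unadjusted p under 0.05, and DESeq2 called 149 higher and 1 lower). Several of the 108 had identical counts, such as ENSMUST00000107991, ENSMUST00000107998 and ENSMUST00000108024, so the number of separate RNAs may be smaller. The transcript ENSMUST00000062945 had 0 counts with IgG and was at least 12.8-fold higher with anti-MAEL, against a floor of 3 counts. For ENSMUST00000040059 the ratio was 59.3 (counting interval 10.4 to 2364), from 117 counts against 1. Both lost the call when either anti-MAEL library was left out. The number of higher transcripts was 63 without anti-MAEL replicate a, and 206 features were higher in the fit of the 3 immunoprecipitates, which also holds loci and noncoding transcripts. One transcript, ENSMUST00000038863, took 26.0% ± 2.40 of anti-MAEL counts and 25.8% of IgG counts.

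Against wild-type mRNA, 4052 coding transcripts were higher with anti-MAEL and 3656 lower. IgG against the same mRNA gave 3314 higher and 2967 lower, so the background gave counts of a like size. Which transcripts both share was not tested, and the tables count different parts of a transcript. The transcript ENSMUST00000037996 was at least 4187-fold higher with anti-MAEL, and IgG carried it too, while ENSMUST00000088495 was at least 171.07-fold lower. With library totals the counts were 2589 higher and 6066 lower.

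The size-selected anti-MAEL immunoprecipitates, with no replicate and no IgG of their size, give values only. At 15 to 50 nt, band-named loci took 21.9% of counts, gene-named loci 5.07% and coding transcripts 32.3%. Relative to wild-type small RNA, the median log2 ratio over loci was -1.69 for band-named and -1.14 for gene-named loci, while the log2 ratio of the classes' summed shares was -1.85 for band-named and 0.41 for gene-named loci. The locus pi-D10Wsu102e held the most counts, 1.86%, followed by 10-qC1-2617 with 1.71% and 9-qC-31469 with 1.57%. At 50 to 150 nt, transcripts of up to 150 nt took 65.6% of counts and band-named loci 5.72%. The transcript ENSMUST00000165827 led there with 2.89%.

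In mRNA, 1696 transcripts were higher and 1979 lower in Mael-/- among 11181 tested (edgeR quasi-likelihood, smallest adjusted p = 0.0330). Every call in this comparison thus lay close to the threshold of 0.05, and a somewhat stricter threshold would leave no calls. Large changes were mostly falls, with 602 transcripts lower and 51 higher by more than 4-fold. The transcript ENSMUST00000038782 fell most, from 2474 ± 51.9 to 4.12 ± 3.77 CPM (SD, n = 2), a log2 fold change of -9.44 ± 0.683 (SE; edgeR quasi-likelihood, adjusted p = 0.0330), and ENSMUST00000020965 fell by 4.65 on the log2 scale. The transcript ENSMUST00000046665 rose, with a log2 fold change of 2.51 ± 0.433. For ENSMUST00000046611 the value of 5.38 was carried by Mael-/- replicate b and was 0.77 without it. Without wild-type replicate a, or without b, 0 transcripts were called, and without Mael-/- replicate b 693 were higher. The share of higher calls was 46.1% with TMM, 69.1% with library totals (3287 against 1470), 27.4% with size factors and 27.9% with DESeq2.

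In ribosome footprints, 1102 transcripts were higher and 1988 lower among 9783 tested (edgeR quasi-likelihood), with 554 lower and 20 higher by more than 4-fold. Among transcripts with a mean of at least 5 CPM, ENSMUST00000038782 again fell most, from 347.8 ± 14.2 to 4.53 ± 1.23 CPM, a log2 fold change of -6.43 ± 0.199 (SE; edgeR quasi-likelihood, adjusted p = 1.56e-08). The transcript ENSMUST00000013235 had 77 counts in wild type against 1 in Mael-/-, a ratio of 40.9 (counting interval 7.12 to 1634). The transcript ENSMUST00000166105 rose, with a log2 fold change of 3.75 ± 0.532. The value of ENSMUST00000046611, 4.63, was 0.63 without Mael-/- replicate b. The share of higher calls was 35.7%, against 49.8% with library totals, 20.5% with DESeq2 and 9.37% in a fit with the mRNA libraries (100 against 967). Without wild-type replicate b, 690 were higher.

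Changes in mRNA and footprints were correlated across the 9627 transcripts tested in both (Pearson 0.815, Spearman 0.780, across transcripts, which are not independent replicates). The slope of footprint change on mRNA change was 0.712, and 81.1% of transcripts had the same sign in both. Both assays called 686 transcripts higher, where independent lists would share 179, and 1159 lower, where they would share 327. Only 1 was higher in mRNA and lower in footprints, and 3 the reverse. For the ratio of footprints to mRNA, 0 of 11427 transcripts passed the test (edgeR quasi-likelihood, smallest adjusted p = 0.602). At an unadjusted p under 0.05 there were 915, DESeq2 called 49 higher and 1 lower, and without Mael-/- mRNA replicate a 146 were higher and 32 lower. On simulated counts the test recovered 27% of 4-fold and 0% of 2-fold changes in this ratio, so the count of 0 does not show that the ratio was unchanged.

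**Figure D4:**
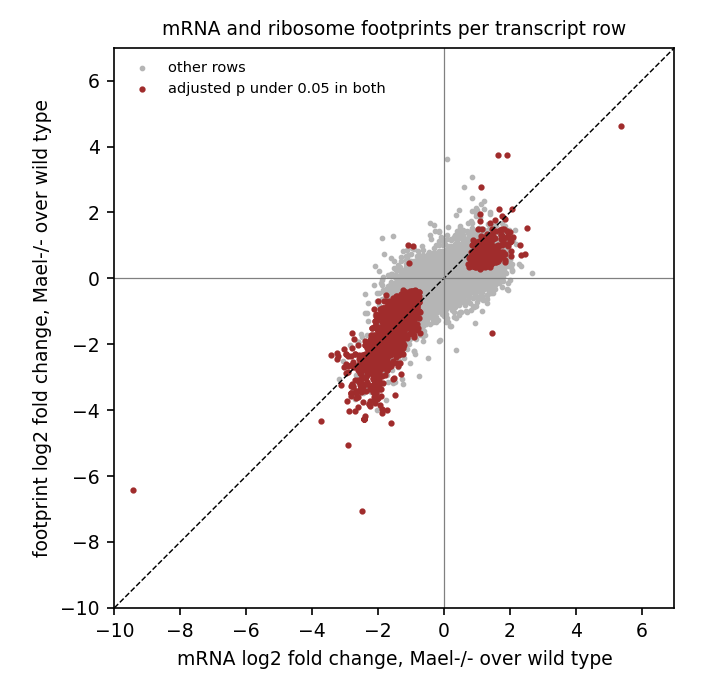
Log2 fold change (Mael-/- over wild type) of each transcript in mRNA and in ribosome footprints; the dashed line marks equality. The values rise together, with Pearson 0.815 across 9627 transcripts.

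The last comparison asked whether transcripts higher with anti-MAEL than with IgG changed without MAEL. In mRNA, 40 of the 90 measured fell and 2 rose, with a median log2 fold change of -0.82 against 0.22 for other transcripts (camera, adjusted p = 1.94e-06), a call lost with an estimated correlation (adjusted p = 0.105). In footprints, 17 of 65 fell and 7 rose, with a median of -0.15 against 0.06 (camera, adjusted p = 0.195). In small RNA, 11 of 96 fell and 4 rose, with a median of -0.40 against 0.15 (camera, adjusted p = 5.87e-05; 0.556 with an estimated correlation). For the ratio of footprints to mRNA, 0 of 89 were called and the median was 0.26 against -0.19 (camera, adjusted p = 4.80e-07; 0.0805 with an estimated correlation). Because mRNA is the denominator of this ratio, its value is not independent of the fall in mRNA. Only 65 members passed the filter in the footprint comparison, against 89 here. The set was chosen on immunoprecipitates of the same series. With 1 IgG library, binding by MAEL and a peculiarity of that library cannot be told apart for this set.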

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

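The tests of library differences and of locus level were chosen after the result was seen, and the decision rule of the test on mRNA fragments was made stricter, with a bootstrap range, after its value was seen. The level test was first run on wild-type levels and then changed to the mean over the 4 libraries, and its decision rule was rewritten with a bootstrap range after the first value was seen, so both values are given.

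The entries named by 2 GenBank records, which the report does not describe, took a larger share of counts in the anti-MAEL libraries than in the IgG library, which is not of the size class of the size-selected ones. They took 1.49% of counts in the 50 to 150 nt anti-MAEL immunoprecipitate, 1.802% in the 15 to 50 nt one and 0.676% ± 0.139 (SD, n = 2) in the long-RNA ones, against 0.0762% (exact 95% interval 0.0743 to 0.0782) with IgG. Their log2 fold changes over IgG, 3.52 ± 0.929 and 3.58 ± 1.62 (SE), did not pass the test in the fit of the 3 long-RNA immunoprecipitates (edgeR quasi-likelihood, adjusted p = 0.138 and 0.670).

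Band-named loci lay below gene-named loci in Mael-/- small RNA, by -1.70 at the median. Against mRNA fragments at gene-named loci, the 24 loci with the densest small RNA in every library gave -1.47 (bootstrap 95% range -1.67 to -0.21), which leaves fragments open. A difference between libraries whatever the genotype stays open too, since the largest within a genotype was 0.773 in size, between the Mael-/- libraries, against -1.34 to -2.20 between genotypes. The lower level of gene-named loci may account for part. Among loci with a mean of 100 to 3000 CPM over the 4 libraries the difference was -1.56 (bootstrap 95% range -2.06 to -0.84), but that mean includes Mael-/- values. Among loci chosen on wild-type level, which loss of MAEL does not move, it was -0.41 (range -1.02 to -0.0015). Wild-type level is the denominator of the fold change, so that choice leaves out loci scarce in wild type and higher in Mael-/-. It kept 33 gene-named loci with a median of -1.35, against 50 with a median of -0.25. Neither choice settles how much is due to level. Loss of MAEL, and a different mix of germ cells in Mael-/- testis, stay open as untested.

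Band-named loci lay above IgG in the anti-MAEL immunoprecipitates, with a median of 2.33. Random lists of the transcripts nearest in size and level with IgG did not reach it, with a highest median of -0.26 among 10000. How close the matches came was not checked. The band-named 3-qA2-617 spans 69605 nt, while coding transcripts had a median of 1923 nt. For such long loci the lists cannot exclude size, which stays open. Abundance in testis RNA was not matched, because the mRNA counts lack these loci, so it stays open. Binding of these transcripts by MAEL and a peculiarity of the IgG library cannot be told apart, because there was 1 IgG library.

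Transcripts higher with anti-MAEL than with IgG lay lower in Mael-/- mRNA, with a median of -0.82. Transcripts whose immunoprecipitate counts agreed within 10% were joined into 69 families, and the median was still -0.82. That value lay below the 95% range of random lists, -0.12 to 0.51. Possible copies with less similar counts stayed separate, and 55 families held a single transcript. For example, ENSMUST00000169045 and ENSMUST00000062637 share a coding size of 1262 but had 1323 and 1474 IgG counts. Repeated counting of copies that were not joined thus stays open. Abundance in wild-type mRNA does not account for the lower median, since the lowest random list matched on abundance stood at -0.30. The median was below 0 in each pairing of a Mael-/- with a wild-type library, from -0.93 to -0.71. A lower level without MAEL and a lower share of the germ cells that hold these transcripts stay open as untested. Whether MAEL binds these transcripts stays open too, because there was 1 IgG library.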

How the results depend on the processing

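The scaling to short transcripts, the fit of piRNA loci alone, identical entries counted once, the fit without the dominant transcript and the offset for the counted region were chosen after seeing the data. The scaling to microRNA genes was not run, since no names identify them. An alternative set of transcripts enriched with anti-MAEL held the 200 with the largest fold change over wild-type mRNA and a mean of at least 5 CPM with anti-MAEL. It had 3 members tested in mRNA and was not tested there. Unless stated, the cause of a change was not tested. The smallest library, of Mael-/- footprints, held 1668197 counts, and how depth limits each comparison was not tested. Where a group is left with 1 library, that library is assumed to vary like the others.

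The difference of medians between band-named and gene-named loci ranged from -2.07 to -1.44 in small RNA when single replicates were left out, and was 1.63 and 2.22 over IgG with 1 anti-MAEL library at a time. Other scalings shift both classes nearly alike, so they do not test this difference.

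In small RNA, higher and lower calls numbered 378 and 346. Size factors gave 226 higher, no filter 233 and all entries per locus 585. Library totals gave 2449 and 139, the 5 CPM filter 829 and 803, and DESeq2 617 lower. Scaling to short transcripts gave 771 higher, and piRNA loci alone, with fewer features tested, 92 and 72. Leaving out single replicates gave 27 to 1218 higher and 51 to 1067 lower, with the fewest without wild-type replicate a. Band-named loci numbered 0 higher and 18 lower, and gene-named loci 15 and 10. Size factors gave 9 gene-named loci higher. Library totals gave 11 and 46 band-named loci and 70 gene-named higher, and no filter gave 7 band-named lower and 2 and 3 gene-named. The 5 CPM filter gave 3 and 83 band-named and 34 and 36 gene-named, and DESeq2 gave 2 and 76 band-named and 29 gene-named lower. Scaling to short transcripts gave 3 and 54 band-named and 35 and 26 gene-named, and piRNA loci alone 14 and 58 band-named and 78 gene-named higher. Leaving out single replicates gave 0 to 5 band-named higher, 0 to 94 band-named lower, 0 to 46 gene-named higher and 2 to 40 gene-named lower.

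In mRNA, size factors gave 710 higher, library totals 3287 and DESeq2 885, against 1696. Leaving out single replicates gave 0 to 1349 higher and 0 to 2728 lower, with 0 without either wild-type library. The spread then came from the Mael-/- pair, whose a minus b differences had an SD of 0.713 against 0.447 in wild type. In footprints, library totals gave 1731 higher and DESeq2 373, against 1102, and the fit of 8 libraries 100 higher and 967 lower. Leaving out single replicates gave 690 to 775 higher and 1630 to 1963 lower. For the ratio of footprints to mRNA, no filter gave 2 and 1, DESeq2 49 and 1, and leaving out single replicates 0 to 146 higher and 0 to 32 lower, the highest without Mael-/- mRNA replicate a.

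For anti-MAEL over IgG, no filter gave 263 higher and 6 lower and DESeq2 1 lower, against 108 and 0. The fit of only the compared groups gave 206 higher, but it also held loci and noncoding transcripts, with 16066 features tested against 12431. Leaving out single replicates gave 63 to 150 higher and 0 to 2 lower, 2 without either wild-type mRNA library. Against mRNA, library totals gave 2589 higher and 6066 lower. For piRNA loci over IgG, against 10 band-named and 6 gene-named, size factors gave 22 and 10, library totals 2 and 0, no filter 63 and 16, the 5 CPM filter 18 band-named, and DESeq2 66 and 11. No call could be made for single anti-MAEL libraries there.

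With an estimated correlation, camera's adjusted p was 0.795 for band-named loci in small RNA, and over IgG 0.408 for band-named loci, 0.432 for gene-named loci and 0.408 for the 50 features most abundant in the 15 to 50 nt anti-MAEL immunoprecipitate. For transcripts higher with anti-MAEL than with IgG, camera's adjusted p was 0.556 in small RNA, 0.105 in mRNA and 0.0805 for the ratio. Fry gave these transcripts an unadjusted p of 0.316 in small RNA, 0.0147 in mRNA, 0.0506 in footprints and 0.0146 for the ratio. Band-named loci had an unadjusted p of 0.0943 in small RNA and 0.181 over IgG with fry. With that set of 200 over mRNA, camera's adjusted p was 0.589 in small RNA, with 49 members measured, 0.563 in footprints, with 6 members and the direction reversed, and 0.563 for the ratio, with 8. For the ratio, the median of that set was -0.33 although camera ranked it upward.

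With the replicate letter as a replicate block, small RNA gave 2318 higher and 1754 lower, with 4 and 79 band-named and 47 and 38 gene-named loci. The block gave 2766 and 2654 in mRNA, 771 and 1723 in footprints, and 0 and 0 for the ratio. The labels do not say that the letters pair samples. The a minus b differences of the genotypes correlated by 0.709 in small RNA, 0.256 in mRNA and -0.127 in footprints.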

Other observations

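A few band-named loci went against their class, a choice made after their values were seen. The locus 13-qA5-208 stood at 1720 ± 48.5 CPM (SD, n = 2) in wild type and 12129 ± 188 CPM in Mael-/-, a log2 fold change of 1.64. It passed the test when adjusted over the list alone (edgeR quasi-likelihood, adjusted p = 0.0337), and with library totals over all features. The locus 3-qA2-617 had a log2 fold change of 1.73 and 2-qE5-4 one of 1.26. Both also passed when adjusted over the list alone (edgeR quasi-likelihood, adjusted p = 0.0245 and 0.0251), and with library totals over all features.

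A hypothesis written before the result was seen held that loci more enriched by anti-MAEL would fall further in Mael-/- small RNA. Across 99 band-named loci, Spearman's rho between enrichment and change was 0.362 (permutation p = 2.8e-04, adjusted 5.4e-04 over 3 relations), the opposite of the predicted sign. Pearson's r was 0.24 (permutation p = 0.014), and rho given the wild-type level was 0.36 (permutation p = 3.6e-04, adjusted 5.4e-04). Loci are not independent replicates, and enrichment itself was higher at loci of higher wild-type level (rho 0.451).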
